A study of Danio rerio with 13 samples.

How the data were processed

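RNA from hearts of zebrafish embryos at 3 days after fertilization was measured on 13 1-colour Affymetrix zebrafish arrays, 1 array per sample. Embryos had been injected at the 1-cell stage, per the labels' protocols, with a control morpholino or with a morpholino against atg5, becn1 or atg7, and a further group was not injected. A morpholino is a synthetic antisense oligonucleotide that blocks the translation or the splicing of its target RNA. Which of these each morpholino blocked was not given in the sources used here. The title of becn1 3 gives the gene as becn, and it was taken as becn1. The hearts were purified from whole embryos and biotin-labelled cRNA was made from 5 ug of total RNA, per the labels' protocols. The groups held 3 uninjected, 2 control morpholino, 3 atg5, 3 becn1 and 2 atg7 arrays. Arrays are named by their group and the replicate number of their title. The labels call the samples biological replicates and do not say how many embryos went into each, so p-values measure the spread between these preparations.

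The values the authors deposited were linear signal intensities per probe set, made with Affymetrix's MAS5 per the submitters' processing notes, with no version and no scaling target given. All deposited intensities were above 0 and there were no detection calls. Between 25.3% and 35.6% of probe sets on an array lay under 16, and differences that rest on weaker signals have no exact size. For named genes under 16 on any array of a comparison the difference is given floored, with normalized intensities under 16 set to 16, or not at all. This was chosen after the data were seen, and the tests and adjusted p are those of the values without it. The trimmed mean intensity over probe sets ran from 93.3 to 198 between arrays, a 2.12-fold range, while the hybridization spike-in controls ran from 611 to 748 (coefficient of variation 6.46%). The arrays therefore had not been scaled to 1 target. The plan, written before the data were examined, called for quantile normalization in that case. The log2 intensities of the 13 arrays were quantile normalized, with no pseudocount. The number of arrays limits the precision of every value.

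The table held 15617 probe sets, of which 115 controls were left out. Probe sets were named through the platform annotation and the current gene table. Of the 15502 analysed, 10795 had 1 gene symbol, 135 had several and 4572 had none. A probe set was kept if its log2 intensity exceeded the 40th percentile of its own array on at least 2 of the 13 arrays, which left 10307 probe sets (66.5%), 7669 of them with 1 symbol, for 6676 genes. With no effect at all, 515 of them would have an unadjusted p under 0.05.

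Group means were fitted to all 13 arrays with limma 3.58.1 (R 4.3.3) with a mean-dependent prior variance, which gave 8 residual and 4.61 prior degrees of freedom. Tests were two-sided, and p-values were adjusted by Benjamini and Hochberg over the 10307 probe sets of each comparison. A probe set was called at an adjusted p under 0.05. No tool other than limma was run on single probe sets. The comparisons were each knockdown against control morpholino, the 3 knockdowns together against control morpholino and against uninjected, control morpholino against uninjected, and the knockdowns against each other. In the pooled comparisons the 3 knockdown groups had equal weight. Levels are log2 intensities after normalization and differences are given with their standard error (SE).

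The comparisons, the tests, the gene lists and the rule for named genes were fixed before the data were examined. List tests were planned for the comparisons against control morpholino and for control morpholino against uninjected. Those for the 3 knockdowns together against uninjected were not in that plan. Named in each comparison were the 3 targeted genes and a set of heart development genes, and the 6 probe sets with the smallest p in each direction among those called whose arrays did not overlap between the sides. Where none was called, the 5 with the smallest p in each direction were named as values. Up to 4 called members of each list were named, or 2 as values. Probe sets without a symbol were skipped. There were 21 lists of pathways and heart cell types and 10 lists of markers of tissues that a heart preparation could hold, of which 902 of 1312 genes were on the array. Each gene of a list was represented by its probe set with the highest mean. Lists with at least 5 members kept were tested against all other genes with limma's camera, with a preset correlation of 0.01, and adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list's own genes move one way, were run beside it. In 30 of the 186 list tests the median, the mean and camera's direction differed in sign, and 0 of these were called.

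The procedure was tested on simulated data made from the real probe sets' means and spread, with 200 of the 10307 probe sets changed in each of 5 draws and probe sets independent of each other. For atg7 against control morpholino, 29.6% of changes of 2-fold, 91.0% of 4-fold and 96.4% of 8-fold were recovered, with 3.86% of calls false. The recovery at 2-fold was 35.5% for atg5, 38.2% for becn1 and 53.4% for the 3 knockdowns together against control morpholino. It was 35.8% for control morpholino and 68.4% for the 3 knockdowns together against uninjected, with 4.32% of calls false in the last.

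The replicate numbers in the titles were checked for pairing through the correlation of deviations from the group means, which is across probe sets. For atg5 and becn1, which were compared directly and share 3 numbers, the correlations were 0.42, 0.12 and 0.14. All exceeded the threshold of 0.1 set for pairing, and a block for the number left the count for atg5 against becn1 at 0. Of all 22 pairs of arrays sharing a number, 12 exceeded 0.1, with a range from -0.41 to 0.62, and all 7 pairs of 2 knockdown arrays were among the 12. The pairs are not independent, since deviations from a group's mean cancel out over its arrays and are mirror images in groups of 2. No batch was named in the labels, and no 2 arrays held identical values.

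Alternatives written beforehand were log2 of the intensity plus 16, median centring, no filter, a filter at the 60th percentile, a replicate block, array weights, a fit of the compared groups alone, a 2-fold minimum, both control groups taken as 1, and each array left out in turn. Chosen after the data were seen were the values on their deposited scale, the 3 knockdown arrays numbered 1 left out, the mean of the heart genes myl7, cmlc1 and tnnt2a as a covariate, and uninjected arrays as the control of each knockdown. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.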

Results

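Gene expression was measured in hearts purified from 3-day-old zebrafish embryos in which a core autophagy gene had been targeted by a morpholino. Atg5 and Atg7 belong to the machinery that conjugates Atg12 and LC3 to build the autophagosome, and Beclin 1 (becn1) is part of the lipid kinase complex that starts it. The series title names the role of autophagy in heart morphogenesis as its subject, and the comparisons ask what each knockdown changed in the heart against a control morpholino and against uninjected embryos. Groups held 2 or 3 arrays each. Median intensities ran from 32.4 to 65.4 between arrays. The ratio of 3' to 5' signal for GAPDH, a sign of RNA integrity, was at most 3.28 on 12 arrays and 5.98 on atg7 2. For the muscle actin acta1 it was higher on every array. It was 28.9 and 29.9 on control 2 and control 3, 86.2 on atg7 2 and 8.03 to 27.4 on the other arrays. The array most like a given array, by correlation across probe sets (0.874 to 0.982 over all pairs), was in its own group for 3 of 13 arrays. Transcripts of other tissues, retina, liver, skeletal muscle and skin among them, were measured in every group. On the uninjected and control morpholino arrays the mean log2 level was 9.07 to 9.66 for neuron and glia markers and 9.29 to 9.66 for epidermis markers. It was 5.27 to 6.37 for 9 heart-restricted genes, a set chosen after the data were seen. Levels of different genes do not give tissue shares, and the word hearts below names the preparations as labelled.

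The targeted atg5 transcript stayed near its control level. Its log2 level was 8.21 ± 0.06 (SD, n = 3) on the atg5 arrays, 8.04 ± 0.25 (SD, n = 2) with control morpholino and 8.03 ± 0.12 (SD, n = 3) uninjected, and the difference of 0.17 from control morpholino (SE 0.17) was not called. A morpholino need not lower its target's mRNA, so this level does not check the labels. becn1 and atg7 have no named probe set here. Of the heart development genes fixed for naming, foxn4, a transcription factor of the atrioventricular canal, had differences of 0.07 (SE 0.38) in atg5, 0.80 (SE 0.38) in becn1 and 1.08 (SE 0.41) in atg7 hearts against control morpholino, with none called. A second foxn4 probe set had differences of -0.30 (SE 0.52), 0.29 (SE 0.52) and 0.14 (SE 0.57). foxn4 is also among the 42 neural progenitor genes listed after the data were seen. Their medians were -0.02, 0.30 and 0.43 in the same comparisons, so its values do not single out the canal. The canal's repressor tbx2b and its ligand bmp4 differed by -0.18 (SE 0.25) and -0.00 (SE 0.46) in atg5, 0.06 and -0.25 in becn1, and 0.27 and -0.25 in atg7 hearts. myl7, the cardiac myosin light chain, had an SE of at least 1.05, since its level was 9.84, 9.59 and 10.06 on atg5 1, becn1 1 and atg7 1 and at most 8.43 on the other 10 arrays. tbx5a, has2 and notch1b lay below the intensity filter, and vcana, nppa, vmhc and myh6 had no named probe set.

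In atg5 morphant hearts the tissue lists called by camera, with the preset correlation alone, were of liver and yolk, retina, cartilage, muscle and pancreas. The 12 lens and retina genes had a median log2 difference of -1.10 from control morpholino, with 11 of them lower. All 22 liver and yolk genes, such as those of plasma proteins and apolipoproteins, were lower, with a median of -0.75. The 14 cartilage and neural crest genes had a median of -0.49. Extracellular matrix (median -0.15), skeletal muscle (median -0.35) and exocrine pancreas (median -0.64) made up the other 3 of 6 lists called by camera, with adjusted p from 0.000147 to 0.0335. With an estimated correlation the adjusted p of each was 0.952, no member was called over all probe sets, and 0 members passed when adjusted over the list alone. The autophagy genes had a median of -0.04 (adjusted p = 0.915) and the lysosome genes 0.02 (adjusted p = 1). Limma called 0 of 10307 probe sets, with 248 at an unadjusted p under 0.05. Those with the smallest p included the ribosomal protein paralog rpl22l1 (0.26, SE 0.07), the actin bundler fscn1a (1.01, SE 0.27), the collagen gene col1a2 (-0.70, SE 0.19), the spectrin gene sptbn1 (-1.02, SE 0.26) and the cone phosphodiesterase gene pde6ha (4.01-fold lower). Also among them were vsir (0.91, SE 0.23), swt1 (under an intensity of 16 on 1 control array), gid8a (0.69, SE 0.18), gpd1c (-1.13, SE 0.33) and tgm1l4, which lay under 16 on every atg5 array. The list count of 6 was 2, 10, 12, 3 and 2 without control 2, control 3, atg5 1, atg5 2 and atg5 3. Extracellular matrix genes lay at -0.26 without atg5 1, and, with the call lost, at -0.13 without atg5 3, -0.11 without control 2 and -0.05 without atg5 2. Skeletal muscle genes lay at -0.90 without control 3, and, with the call lost, at -0.36 without atg5 2, -0.22 without atg5 3 and 0.15 without control 2. Liver and yolk genes lay at -1.46 without atg5 1 and -1.34 without control 3, and, with the call lost, at -0.39 without atg5 3 and 0.04 without control 2. Exocrine pancreas genes lay at -1.50 without atg5 1, and, with the call lost, at -0.79 without control 2, -0.52 without control 3, -0.50 without atg5 3 and -0.24 without atg5 2. Lens and retina genes lay at -0.91 without control 2, with the call lost. Cartilage and neural crest genes lay at -0.24 without atg5 1.

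Preparations of becn1 morphant hearts had lower transcripts of cone and rod photoreceptors. The 12 lens and retina genes were all lower than with control morpholino, with a median of -2.18. They included the cone phosphodiesterase gene pde6ha (-3.14, SE 0.66). They also included the cone transducin gene gnat2, the cone phosphodiesterase gene pde6c and the ultraviolet and green opsin genes opn1sw1 and opn1mw1, whose signals on becn1 1 were too weak for an exact difference. With intensities under 16 set to 16, called floored from here on, their differences were -3.36, -2.54, -3.52 and -3.65. Among these 12 genes, 0 were called over all probe sets and 9 fell when adjusted over the list alone. The camera adjusted p was 1.41e-10 and the adjusted p was 0.474 with an estimated correlation. Liver and yolk genes (median -1.13, 21 of 22 lower), exocrine pancreas (median -1.82), cartilage and neural crest (median -0.84) and intestine and pronephros (median -0.41) were lower in the same test. So were smooth muscle and outflow tract (-0.81), neuron and glia (-0.23), epidermis (-0.21), fatty acid oxidation (-0.15), extracellular matrix (-0.11) and oxidative phosphorylation (-0.09), while the 59 cell cycle genes lay higher (median 0.24). Adjusted p ran from 1.49e-06 to 0.0481 for these 11 lists, and was 0.711 or 0.766 with an estimated correlation, with 0 of their members past the threshold over all probe sets or when adjusted over the list alone. The autophagy and lysosome lists were not called. Limma called 0 probe sets, with 544 at an unadjusted p under 0.05. The smallest p-values were those of znf395a, a zinc finger gene (1.46, SE 0.23, adjusted p = 0.343), gnb3b, the cone transducin beta subunit (-3.06, SE 0.54), and rcvrn3, a recoverin (-2.14 floored), with rpl22l1 (0.34, SE 0.07), taf1c (0.83, SE 0.20), the brain proteoglycan gene ncana (1.31, SE 0.31), the chemokine gene ccl34b.1 (-1.91, SE 0.40) and the mucin gene muc5.2 (-2.15, SE 0.48) among them. Leaving out control 2 lowered the 12 called lists to 5. Smooth muscle and outflow tract genes lay at -0.59 without becn1 2, -0.50 without becn1 3 and -0.28 without control 2, with the call lost. Oxidative phosphorylation genes lay at -0.16 without becn1 1 and -0.15 without control 3, and, with the call lost, at -0.07 without control 2 and -0.02 without becn1 3. Fatty acid oxidation genes lay at -0.23 without control 3, and, with the call lost, at -0.15 without becn1 3 and -0.13 without control 2. Cell cycle genes lay at 0.38 without becn1 3 and 0.48 without control 3, and, with the call lost, at 0.01 without becn1 1 and 0.05 without control 2. Extracellular matrix genes lay at -0.19 without becn1 1 and -0.18 without control 3, and, with the call lost, at -0.13 without control 2 and -0.00 without becn1 2. Epidermis genes lay at -0.39 without becn1 2, and, with the call lost, at -0.04 without becn1 1. Liver and yolk genes lay at -1.85 without control 3 and -1.75 without becn1 1, and, with the call lost, at -0.35 without control 2. Exocrine pancreas genes lay at -1.65 without control 3 and -1.31 without becn1 2, with the call lost. Neuron and glia genes lay at -0.45 without becn1 3 and -0.37 without becn1 2, and, with the call lost, at -0.13 without control 2 and 0.02 without becn1 1. Lens and retina genes lay at -1.31 without becn1 1. Cartilage and neural crest genes lay at -0.51 without control 2, and, with the call lost, at -0.77 without control 3 and -0.47 without becn1 1. Intestine and pronephros genes lay at -0.78 without control 3 and -0.71 without becn1 1, and, with the call lost, at -0.25 without becn1 2 and -0.19 without control 2. The count of 0 became 1 without becn1 3 and 14 when both control groups were taken as 1.

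In atg7 morphant hearts 6 probe sets were called. The count was 0 with a block for the replicate number, with only the compared groups fitted, or with the stricter intensity filter, so these calls depend on the model. Of the 6 called, 5 were higher and 1 lower. The balance turned to 9 higher and 20 lower on the deposited scale, 10 and 25 with the heart genes as a covariate, and 3 and 6 without the arrays numbered 1. gnb3b, the beta subunit of cone transducin, fell from 8.60 ± 0.22 (SD, n = 2) to 4.49 ± 0.64 (SD, n = 2), a difference of -4.11 (SE 0.59, limma adjusted p = 0.0433). cnot10, a subunit of the CCR4-NOT deadenylase, rose by 1.49 (SE 0.23) and si:ch211-132d3.4 by 1.43 (SE 0.22), each with an adjusted p of 0.0433, and 3 probe sets without a symbol rose. The lens and retina list had a median of -2.18, with 0 of 12 genes called over all probe sets and 9 lower when adjusted over the list alone, among them gnat2, pde6c and opn1sw1. These 3 were too weak on 1 or both atg7 arrays for an exact difference, and the floored differences were -4.49, -3.53 and -5.25. The lens genes of the list, cryba4 (0.55), crybb1 (0.74) and bfsp2 (1.23), lay higher, with none called. The camera adjusted p of this list was 5.32e-07 and the adjusted p was 0.63 with an estimated correlation. The matrix metalloproteinase genes mmp13a (2.36) and mmp9 (1.83), which leukocytes and injured tissue express, rose when adjusted over the extracellular matrix list alone, with 0 called over all probe sets, while the list itself had a median of -0.30 (camera adjusted p = 0.00232) and an adjusted p of 0.63 with an estimated correlation. Cell cycle genes (median 0.52, 58 of 59 higher), the proteasome (0.33, 46 of 49 higher) and leukocyte markers (0.50, 12 of 13 higher) lay higher. Epidermis (-0.35, 24 of 24 lower), neuron and glia (-0.48), liver and yolk (-0.73), cartilage and neural crest (-0.68) and skeletal muscle (-0.46) lay lower. Of these 8 lists, the synuclein gene sncgb (-1.60) alone passed when adjusted over the list alone, the camera adjusted p was at most 0.0126, and the adjusted p was 0.63 or 0.713 with an estimated correlation. The autophagy and lysosome lists were not called. atg7 2 had the highest ratios of 3' to 5' signal, 5.98 for GAPDH and 86.2 for acta1, against at most 2.99 and 29.9 on the 5 control arrays. The count of 6 became 0 without control 2, control 3 or atg7 2, 1 without atg7 1, 0 with no filter and 137 with both control groups as 1. Without control 2 the called lists numbered 6 in place of 10. Cell cycle genes lay at 0.30 without control 2. Extracellular matrix genes lay at -0.53 without atg7 1, and, with the call lost, at -0.32 without control 2 and -0.15 without atg7 2. Skeletal muscle genes lay at -0.998 without control 3 and -0.74 without atg7 1, and, with the call lost, at -0.03 without atg7 2 and 0.08 without control 2. Epidermis genes lay at -0.73 without atg7 2, and, with the call lost, at -0.18 without atg7 1. Liver and yolk genes lay at -1.83 without atg7 1 and -1.44 without control 3, and, with the call lost, at -0.18 without control 2 and 0.31 without atg7 2. Neuron and glia genes lay at -0.81 without atg7 2 and -0.11 without atg7 1. Leukocyte genes lay at 0.31 without control 2 and 0.43 without atg7 1, with the call lost.

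Across the 3 knockdowns together, photoreceptor transcripts were the lowest group against control morpholino. gnb3b differed by -2.81 (SE 0.47) and pde6ha by -2.60 (SE 0.58), and, with weak signals on some knockdown arrays, rcvrn3 by -1.94 and the phosducin gene pdcb by -2.81 floored, with no call for any (smallest adjusted p 0.501). Higher values with the smallest p were those of si:ch211-132d3.4 (0.84, SE 0.18), rpl22l1 (0.27, SE 0.06), znf395a (0.86, SE 0.20), ncana (1.15, SE 0.27) and znf532 (0.82, SE 0.20), and the mitochondrial carrier gene slc25a3a was lower (-2.17 floored). The lens and retina genes had a median of -1.71, with 0 of 12 called over all probe sets, 9 lower when adjusted over the list alone, a camera adjusted p of 1.08e-09, and an adjusted p of 0.579 with an estimated correlation. Liver and yolk (-0.81), cartilage and neural crest (-0.76), exocrine pancreas (-1.28), skeletal muscle (-0.38), neuron and glia (-0.26), intestine and pronephros (-0.26), epidermis (-0.23) and extracellular matrix (-0.20) were also lower. Cell cycle (0.21), leukocyte (0.25) and proteasome (0.15) genes were higher. The adjusted p of these 11 lists was 0.657 with an estimated correlation, and the members that passed when adjusted over the list alone were col1a2 (-0.66), mmp13a (1.38) and the bile acid binding gene fabp6 (-1.31 floored, under 16 on 7 of the 8 knockdown arrays), with 0 over all probe sets. Limma called 0 probe sets, with 559 at an unadjusted p under 0.05, and 1 without becn1 1 or without becn1 3. With both control groups as 1 the count was 94, and without control 2 the called lists numbered 5 in place of 12. Cell cycle genes lay at 0.14 without becn1 1 and 0.43 without control 3, and, with the call lost, at 0.06 without control 2. Proteasome genes lay at 0.14 without control 2, with the call lost. Extracellular matrix genes lay at -0.15 without control 2 and -0.09 without atg7 2, with the call lost. Skeletal muscle genes lay at -0.93 without control 3, and, with the call lost, at -0.22 without atg7 2, -0.21 without becn1 1 and 0.18 without control 2. Epidermis genes lay at -0.35 without atg7 2 and -0.14 without atg7 1. Liver and yolk genes lay at -1.66 without control 3, -1.23 without atg7 1 and -0.44 without atg7 2, and, with the call lost, at -0.22 without control 2. Exocrine pancreas genes lay at -1.09 without becn1 2, -1.01 without control 3 and -0.77 without atg7 2, with the call lost. Neuron and glia genes lay at -0.39 without atg7 2, -0.16 without control 2 and -0.15 without atg7 1. Leukocyte genes lay at 0.05 without control 2, 0.18 without atg5 1, 0.19 without atg7 1, 0.20 without becn1 3, 0.22 without atg7 2 and 0.22 without becn1 1, with the call lost. Intestine and pronephros genes lay at -0.45 without control 3 and -0.43 without atg7 1, and, with the call lost, at -0.22 without becn1 2, -0.21 without becn1 3, -0.19 without atg5 3, -0.17 without atg5 2, -0.11 without atg7 2 and 0.04 without control 2.

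Between control morpholino and uninjected hearts camera called 9 lists and limma no single probe set. The 59 cell cycle genes had a median of 0.34, with 55 higher, the 49 proteasome genes 0.21, with 41 higher, and the 73 oxidative phosphorylation genes 0.19, with 64 higher. Skeletal muscle (-0.53), cardiac sarcomere (-0.34), glycolysis (-0.20), extracellular matrix (-0.17), atrioventricular canal, cushion and valve (-0.17) and epidermis (-0.15) genes lay lower. These 9 lists had camera adjusted p from 5.27e-08 to 0.0317, and 0.568 or 0.74 as the adjusted p with an estimated correlation, with 0 members called over all probe sets or when adjusted over the list alone. The lens and retina list was not called. Limma called 0 probe sets, with 266 at an unadjusted p under 0.05. The smallest p-values belonged to the splicing gene snrpf (0.77, SE 0.21), tmem230a (0.81, SE 0.22), eef1e1 (0.55, SE 0.16), zgc:193812 and zgc:136864, and to slc16a12b (-0.89, SE 0.26), the elongation factor eef2b (-0.30, SE 0.09), the survival gene bcl2l1 (under 16 in intensity on both control arrays), ddx54 and fbxo11b. Without control 3 the called lists numbered 3. Cardiac sarcomere genes lay at -0.54 without control 2, and, with the call lost, at -0.12 without uninjected 1 and 0.06 without control 3. Atrioventricular canal, cushion and valve genes lay at -0.09 without uninjected 2, and, with the call lost, at -0.10 without control 2. Oxidative phosphorylation genes lay at 0.09 without uninjected 3, with the call lost. Glycolysis genes lay at -0.09 without uninjected 1, and, with the call lost, at -0.06 without control 3. Cell cycle genes lay at 0.56 without control 2, and, with the call lost, at 0.17 without control 3. Extracellular matrix genes lay at -0.15 without control 3, with the call lost. Skeletal muscle genes lay at -1.19 without control 2 and -1.06 without uninjected 2, and, with the call lost, at -0.30 without uninjected 1 and 0.05 without control 3. Epidermis genes lay at -0.23 without uninjected 3, and, with the call lost, at -0.17 without control 3 and -0.14 without uninjected 1.

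Against uninjected hearts the 3 knockdowns together had 73 probe sets higher and 53 lower, 126 of 10307, for 91 named genes. The genes that rose included her4.5, a Notch target of the Hairy/E(spl) family (1.39 floored, under 16 on 2 of the 3 uninjected arrays, adjusted p = 0.0267), the homeobox genes en1b (0.97, SE 0.15, adjusted p = 0.0267) and hoxb9a (0.80, SE 0.13, adjusted p = 0.0277), the tryptophanyl-tRNA synthetase gene wars1 (0.73, SE 0.12), enc3 (0.82, SE 0.13) and si:ch211-132d3.4 (1.03, SE 0.15). The genes that fell included the gel-forming mucins muc5.1 (-1.77, SE 0.23, adjusted p = 0.012) and muc5.2 (-2.58, SE 0.35, adjusted p = 0.012), the keratin gene krt97, from 11.53 ± 0.05 (SD, n = 3) to 10.57 ± 0.28 (SD, n = 8, limma adjusted p = 0.012), the monocarboxylate transporter gene slc16a12b (-1.24, SE 0.19), gnb3b (-2.89, SE 0.40, adjusted p = 0.012) and rcvrn3 (-2.03 floored). Each of these 12 genes separated all 8 knockdown arrays from all 3 uninjected arrays, which was a condition for naming them. Of the 73 higher and 53 lower probe sets, 63 and 43 did so. None of the 12 genes was called for the 3 knockdowns together against control morpholino. Against control morpholino, gnb3b and si:ch211-132d3.4 were called in atg7 hearts. Between control morpholino and uninjected hearts slc16a12b was also lower and her4.5 higher, without a call, and gnb3b differed by -0.07. Against uninjected alone, an effect of the knockdowns cannot be told apart from one of injection. Other called members of the fixed lists were the heart and muscle transcription factors mef2d (-1.12) and mef2aa (-1.01), the scavenger receptor gene marco of macrophages (1.19 floored, under 16 on all 3 uninjected arrays, with the call lost when 16 was added before the log), asparagine synthetase asns (0.94), the glucocorticoid-induced fkbp5 (-1.15) and the ferritin gene fthl27 (0.34). At an unadjusted p under 0.05 limma gave 2539 probe sets. The 126 became 0 without uninjected 1 or uninjected 3. They became 28, 9 and 12 without atg5 1, 2 and 3, 11 without becn1 2, 876 without becn1 3, and 11 and 13 without atg7 1 and 2. The split of 73 higher and 53 lower became 13 and 71 on the deposited scale and 382 and 106 with median centring.

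**Figure D1:**
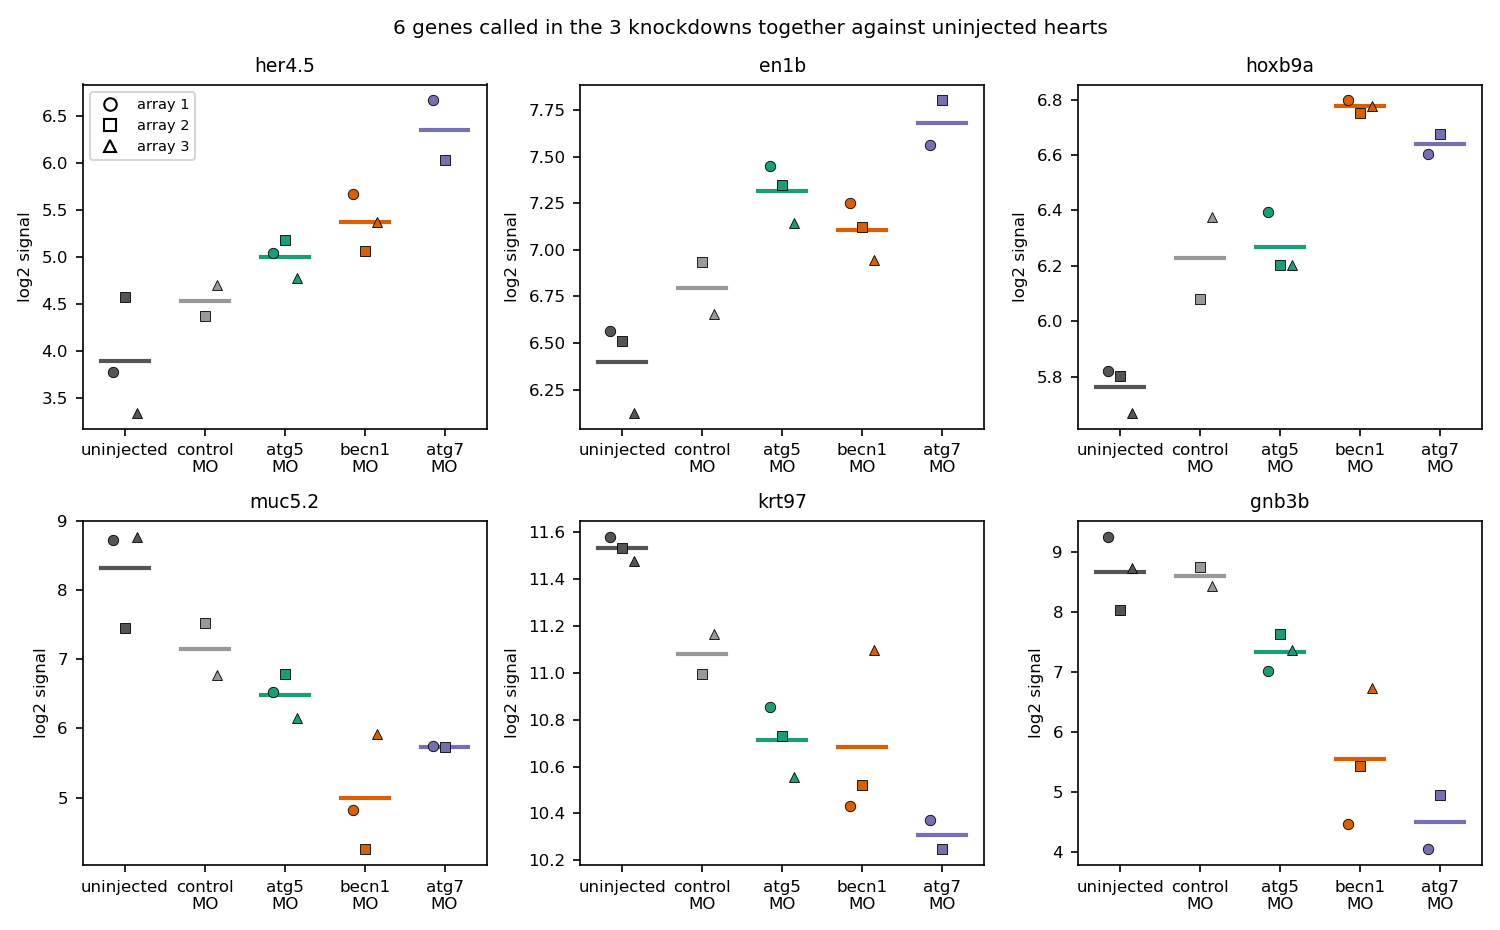
Log2 intensity after quantile normalization of 6 genes called in the 3 knockdowns together against uninjected hearts, with 1 point per array, the point's shape giving the replicate number, and a line at each group's mean. The 8 knockdown arrays lie above the 3 uninjected arrays for her4.5, en1b and hoxb9a and below them for muc5.2, krt97 and gnb3b. This separation was a condition for naming the genes.

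In the same comparison, whose list tests were not in the plan, the cell cycle genes were the group with the largest number past the threshold within their list. They had a median of 0.59, with 58 of 59 higher; ncapg of the condensin complex (1.01, SE 0.20) and the ribonucleotide reductase gene rrm1 (0.84, SE 0.19) were called over all probe sets, and 33 rose and kif20a (-0.85) fell when adjusted over the list alone. Of 49 proteasome and ubiquitin genes 45 were higher, with a median of 0.40, psmd8 (0.67, SE 0.12) called over all probe sets, and 29 higher when adjusted over the list alone, among them psma5 (0.68), psmb1 (0.55) and psmc2 (0.45). Camera gave adjusted p of 2.1e-11 and 5.37e-08 for these lists, and the adjusted p was 0.34 for each with an estimated correlation. Extracellular matrix genes had a median of -0.40, with col1a2 (-0.87, SE 0.14) called over all probe sets, and 11 lower and 2 higher when adjusted over the list alone. The lower ones included col1a1a (-0.73), fbln1 (-1.11) and ccn2b (-1.04 floored), and the higher ones were mmp13a (1.38) and mmp9 (1.09). Epidermis genes had a median of -0.46, with 6 such as epcam (-0.70) lower when adjusted over the list alone and 0 over all probe sets, and the adjusted p of both lists was 0.34 with an estimated correlation. The lens and retina genes had a median of -1.57, with gnat2 (-3.30 floored) and pde6c (-2.90 floored) called over all probe sets, 9 lower when adjusted over the list alone, and an adjusted p of 0.34 with an estimated correlation. These 5 lists kept their call, with a median within 1.5 times, in each of the 11 fits with 1 array left out. However, cell cycle (0.34), proteasome (0.21), extracellular matrix (-0.17) and epidermis (-0.15) were called the same way for control morpholino against uninjected. In the 3 knockdowns together against control morpholino their medians were 0.21, 0.15, -0.20 and -0.23. The shifts of these lists from uninjected therefore cannot be put down to the knockdowns alone.

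Of the heart's own lists, the cardiac sarcomere genes had a median of -0.18 (17 genes), calcium handling, excitability and natriuretic peptide genes -0.41 (8 genes), smooth muscle and outflow tract genes -1.05 (5 genes) and atrioventricular canal, cushion and valve genes -0.05 (28 genes), all called by camera with adjusted p from 0.0143 to 0.0373. With an estimated correlation the adjusted p was 0.598 for the sarcomere and 0.34 for the other 3. The sarcomere mean differed within the knockdowns, at 7.83, 7.46 and 8.07 on atg5 1, becn1 1 and atg7 1 and 6.47 to 7.02 on the other 5 knockdown arrays. The 9 heart-restricted genes went the other way, with a median of 0.23 and 7 of 9 higher, and were not called (camera adjusted p = 0.801). When adjusted over the list alone, tagln (-1.09), acta2 (-1.09), tpm1 (-1.05) and smtnb (-0.51) of smooth muscle fell. Of the valve list the flow-responsive klf2a (-0.67) and klf2b (-0.78), col1a2, fbln1 and ctnnb1 fell. In the same list sox9b (0.68) and foxn4 (0.83), also a neural progenitor gene, rose, and col1a2 alone was called over all probe sets. Skeletal muscle (-0.98), liver and yolk (-0.84), exocrine pancreas (-1.43), cartilage and neural crest (-0.81), intestine and pronephros (-0.44), neuron and glia (-0.28) and glycolysis (-0.19) genes were lower, and leukocyte (0.39) and oxidative phosphorylation (0.20) genes higher. With an estimated correlation the adjusted p of these 9 lists lay between 0.34 and 0.738. Over all probe sets 1 member was called in neuron and glia (sncgb), 1 in leukocyte (marco) and 0 in the other 7, and when adjusted over the list alone the counts lower were 2, 0, 4, 4, 1, 1 and 0 and the counts higher 2 and 0 in the order given, with ptf1a of the pancreas list higher. On the 13 arrays the skeletal muscle, liver and pancreas markers also differed between arrays of 1 group, as in the liver and yolk mean of 9.60 on uninjected 1 and 8.16 on uninjected 3. Without uninjected 1 the called lists fell from 18 to 11. Cardiac sarcomere genes lay at -0.52 without atg7 1, -0.33 without atg5 1 and -0.30 without uninjected 3, and, with the call lost, at -0.15 without atg5 3, -0.13 without becn1 2, -0.12 without atg5 2, -0.10 without uninjected 1 and 0.03 without atg7 2. Atrioventricular canal, cushion and valve genes lay at -0.15 without atg7 1, -0.15 without uninjected 3, -0.10 without atg5 1, -0.09 without becn1 1, -0.03 without atg5 3, -0.03 without becn1 3 and -0.03 without atg5 2, and, with the call lost, at -0.04 without uninjected 2 and 0.00 without atg7 2. Calcium handling genes lay at -0.34 without uninjected 1, with the call lost. Smooth muscle and outflow tract genes lay at -0.65 without uninjected 1, with the call lost. Oxidative phosphorylation genes lay at 0.08 without uninjected 3, 0.17 without becn1 2 and 0.19 without atg5 1, with the call lost. Glycolysis genes lay at -0.18 without atg5 2 and -0.13 without uninjected 1, with the call lost. Skeletal muscle genes lay at -0.58 without uninjected 1. Liver and yolk genes lay at -0.48 without atg7 2, and, with the call lost, at -0.31 without uninjected 1. Exocrine pancreas genes lay at -1.31 without uninjected 1 and -1.21 without uninjected 2, with the call lost. Neuron and glia genes lay at -0.47 without uninjected 2 and -0.16 without uninjected 3. Cartilage and neural crest genes lay at -0.41 without uninjected 1. Leukocyte genes lay at 0.35 without atg5 1, 0.38 without becn1 1, 0.41 without atg7 1 and 0.47 without becn1 3, with the call lost. Intestine and pronephros genes lay at -0.24 without atg7 2, and, with the call lost, at -0.37 without uninjected 1.

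**Figure D2:**
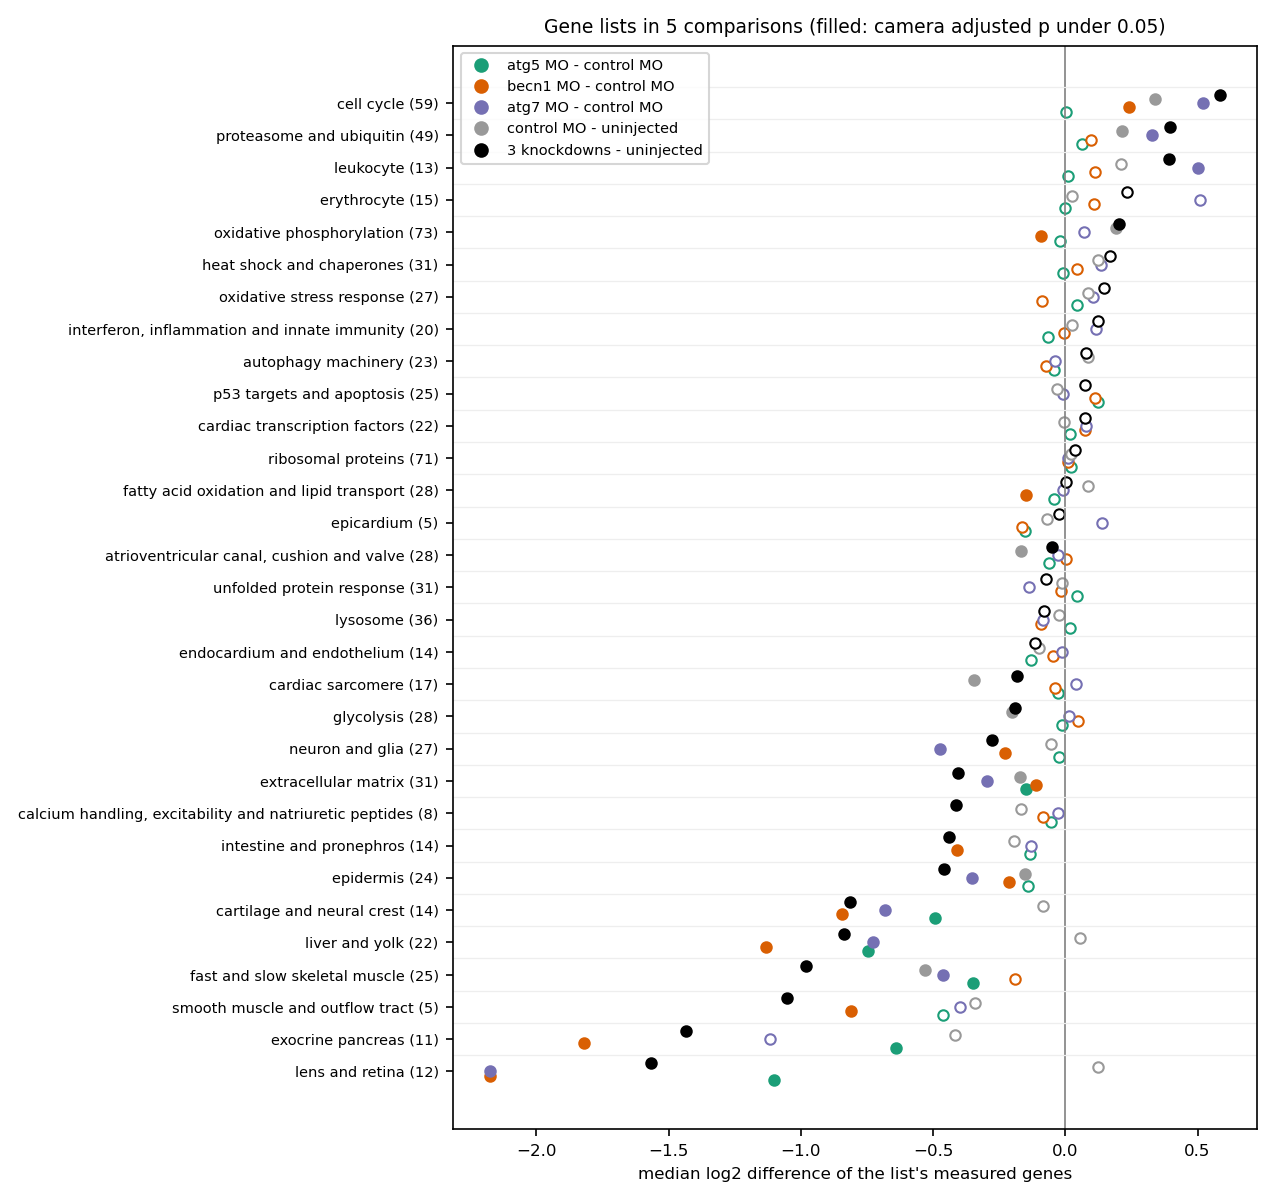
Median log2 difference of the measured genes of each fixed list, with the number of genes in brackets, in 5 comparisons. Filled points had a camera adjusted p under 0.05 with the preset correlation. The lens and retina list lies at -1.10, -2.18 and -2.18 in the 3 knockdowns against control morpholino and the cell cycle list at 0.59 in the 3 together against uninjected.

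Between the knockdowns few probe sets were called, and none had a symbol. atg5 and becn1 hearts differed in 0 probe sets, with 630 at an unadjusted p under 0.05. The smallest p-values were those of the cell death gene bada (1.14, SE 0.27), fxyd6l (0.54, SE 0.12), the rod transducin gamma gene gngt1 (1.71, SE 0.40), micos10 of the mitochondrial inner membrane (0.95, SE 0.23) and rgs5a (0.95, SE 0.24), and lower in atg5 than in becn1 hearts znf395a (-1.07, SE 0.21), far1 (under 16 in intensity on every atg5 array), tex10, serpinb1l3 and tgm1l4. atg5 and atg7 hearts differed in 2 probe sets, both lower in atg5 (9 higher and 5 lower on the deposited scale), with 1212 at an unadjusted p under 0.05. becn1 and atg7 hearts differed in 2, with 1 in each direction (0 higher and 2 lower on the deposited scale) and 449 at an unadjusted p under 0.05. For atg5 against atg7 the count of 2 became 0 without atg5 1, atg5 2 or atg7 2 and 1 without atg5 3 or atg7 1. For becn1 against atg7 it became 0 without any becn1 array or atg7 2 and 1 without atg7 1.

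The log2 changes of the knockdowns against control morpholino correlated across the 10307 probe sets, which are not independent. Since both use the same 2 control arrays, a correlation arises without any effect, and it was simulated with unchanged groups. It was 0.592 observed and 0.601 simulated for atg5 and becn1, 0.502 and 0.549 for atg5 and atg7, and 0.770 and 0.548 for becn1 and atg7. The covariance was 0.0766 against 0.0680 simulated, 0.0810 against 0.0682, and 0.171 against 0.0679, which leaves 0.00856, 0.0128 and 0.103. The simulation took the knockdown arrays as independent, so likeness between arrays that share a replicate number also adds to the observed values. A split of the 2 control arrays would leave 1 in each part and was not made, and part of the excess may come from the shared controls. With control morpholino for one knockdown and uninjected for the other, the correlation was 0.436 or 0.411 for atg5 and becn1 (covariance 0.0656 or 0.0678), 0.355 or 0.533 for atg5 and atg7 (0.0699 or 0.109), and 0.597 or 0.772 for becn1 and atg7 (0.162 or 0.200). Each of these covariances, with no control array in common, lay above what the subtraction left for its pair. The subtraction therefore does not measure what the knockdowns share. Separate controls do not settle it either, since control 2 was most like uninjected 1 and control 3 most like uninjected 2.

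**Figure D3:**
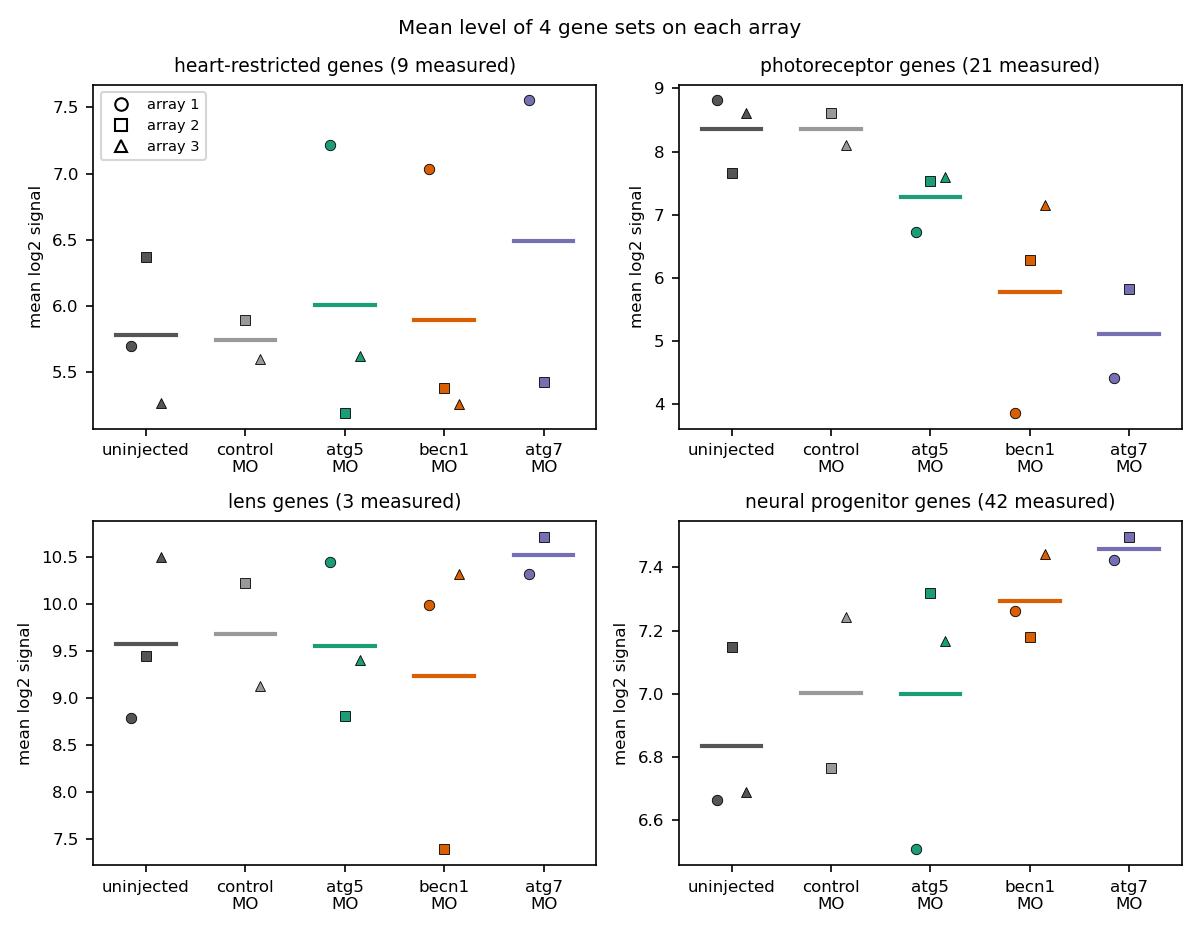
Mean log2 intensity after normalization of 4 gene sets on each array, with 1 point per array, the point's shape giving the replicate number, and a line at each group's mean. Photoreceptor genes lie at 7.66 or more on the 5 control arrays and at 7.60 or less on the 8 knockdown arrays, and heart-restricted genes lie highest on the array numbered 1 of each knockdown.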

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

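The 3 probe sets that differed between knockdowns have no gene symbol in the annotation used, so no function is stated for them. The first had a log2 level of 8.33 in atg7 hearts, 5.41 in atg5 hearts and 5.52 in becn1 hearts, against 5.32 with control morpholino and 5.19 uninjected. It was lower in atg5 than in atg7 hearts by -2.92 (SE 0.375, limma adjusted p = 0.019) and in becn1 than in atg7 hearts by -2.81 (limma adjusted p = 0.0468). The second was at 7.24 in atg7 hearts and under an intensity of 16 on 2 of the 3 atg5 arrays, a difference of -3.29 (limma adjusted p = 0.019), or of -3.07 with intensities under 16 set to 16. The third was higher in becn1 than in atg7 hearts, at 6.60 and 4.82, a difference of 1.78 (SE 0.250, limma adjusted p = 0.0468). What drew attention to each was a tested difference between 2 knockdowns. No call was kept in every fit with 1 array left out: the count for atg5 against atg7 was 0 without atg5 1, atg5 2 or atg7 2, and that for becn1 against atg7 was 0 without atg7 2 or any becn1 array.

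The control probes of 2 transcripts, which the comparisons leave out, set 1 array apart. On atg7 2 the ratio of 3' to 5' signal was 5.98 for GAPDH, against at most 2.99 on the 5 control arrays, and 86.2 for the muscle actin acta1, against at most 29.9. A high ratio is a sign of shortened RNA or of incomplete labelling. The photoreceptor genes had a mean of 5.82 on atg7 2 and 4.41 on atg7 1, whose GAPDH ratio was 2.39. No group held the 4 arrays that a test for a single distant array needs.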

How the results depend on the processing

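None of the 29 named gene results that were called turned direction under an alternative, and called genes that were not named were not followed. The 29 gave 562 values, of which 337 kept the call and 225 lost it, and of 6809 values of 423 named gene results without a call 176 gained one. The 67 called lists gave 1153 values, of which 872 kept the direction and the call, 255 kept the direction without the call and 26 turned direction. Except where said, the cause of each move below was not tested.

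becn1 against control morpholino had no called probe set, and 25 with the replicate block, 14 with both controls, 5 on the deposited scale, 1 with the arrays numbered 1 left out, 12 with the heart genes as a covariate, 1 with uninjected as the control, and 0 to 1 with 1 array left out. atg7 against control morpholino had 6, and 10 with 16 added before the log, 0 with no filter, 0 with the 60th percentile filter, 0 with the replicate block, 11 with array weights, 0 with only the compared groups, 137 with both controls, 29 on the deposited scale (9 higher, 20 lower), 35 with the heart covariate, 317 with uninjected as the control, and 0 to 1 with 1 array left out. The 3 together against control morpholino had no called probe set, and 28 with the replicate block, 94 with both controls, 13 on the deposited scale, 12 with the arrays numbered 1 left out, 10 with the heart covariate, and 0 to 1 with 1 array left out. Both controls together make 5 arrays in place of 2, and the single-array fits and those of only the compared groups have fewer arrays.

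Against uninjected the 3 together had 126 called, and 57 with 2-fold asked for as well, 488 with median centring, 24 with no filter, 327 with the replicate block, 981 with array weights, 14 with only the compared groups, 203 with the arrays numbered 1 left out (68 higher, 135 lower), 446 with the heart covariate, and 0 to 876 with 1 array left out. On the deposited scale 84 were called, 13 higher and 71 lower, and the median over all probe sets shifted by -0.03. That shift was 0.29, 0.33, 0.27 and 0.30 for atg5, becn1, atg7 and the 3 together against control morpholino and -0.32 for control morpholino against uninjected, since the arrays were deposited without a common scale.

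atg5 against atg7 had 2, and 6 with 16 added, 5 with median centring, 0 with the 60th percentile filter, 1 with the replicate block, 15 with array weights, 0 with only the compared groups, 14 on the deposited scale, 0 with the arrays numbered 1 left out, 6 with the heart covariate, and 0 to 1 with 1 array left out. becn1 against atg7 had 2, and 4 with 16 added, 0 with the 60th percentile filter, 0 with the replicate block, 0 with array weights, 0 with only the compared groups, 0 with the arrays numbered 1 left out, and 0 to 1 with 1 array left out. atg5 against control morpholino, control morpholino against uninjected and atg5 against becn1 kept a count of 0, with 0 to 0 over single arrays left out.

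With an estimated correlation 0 lists were called in each of the 6 comparisons. fry called 0 in 5 of them and 6 in the 3 together against uninjected, and its mixed form called 1 for atg7, 0 for the other 4 and 17 against uninjected. For atg5 the 6 lists were 12 with both controls, 10 with the arrays numbered 1 left out and 15 with uninjected as the control. With 1 array left out the lists called ran from 2 to 12 for atg5, 5 to 13 for becn1, 6 to 14 for atg7, 5 to 18 for the 3 together and 3 to 12 for control morpholino against uninjected, and from 11 to 18 for the 3 together against uninjected. The medians of called lists that turned with 1 array left out did so without control replicate 2 for skeletal muscle (0.149 for atg5, 0.0817 for atg7, 0.178 for the 3 together), liver and yolk for atg5 (0.0416) and intestine for the 3 together (0.0441). The other ends of these ranges were -0.902, -0.998 and -0.930 for skeletal muscle and -0.451 for intestine without control replicate 3, and -1.46 for liver without atg5 replicate 1. Without control replicate 3 sarcomere (0.0618) and skeletal muscle (0.0521) turned for control morpholino against uninjected, where they were -0.543 and -1.19 without control replicate 2. Without atg7 replicate 2 liver and yolk turned for atg7 (0.311), and sarcomere (0.0265) and the valve list (0.00132) for the 3 together against uninjected, which without atg7 replicate 1 were -1.83, -0.516 and -0.152. Neuron and glia turned for becn1 without becn1 replicate 1 (0.0227, and -0.453 without becn1 replicate 3) or without the arrays numbered 1 (0.0227), and oxidative phosphorylation for becn1 with both controls (0.000607) or uninjected as the control (0.0897). On the deposited scale, which keeps the shift given above, matrix turned for atg5 (0.104), becn1 (0.194) and the 3 together (0.0622), and epidermis (0.146, 0.0685) and neuron and glia (0.147, 0.0693) for becn1 and the 3 together. There also oxidative phosphorylation (0.253) and fatty acid oxidation (0.146) turned for becn1, intestine for the 3 together (0.0227), and oxidative phosphorylation (-0.0901) and proteasome (-0.102) for control morpholino against uninjected. Detection calls were not used here, so weak signals such as those of tbx5a and notch1b were set aside by intensity alone.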

Other observations

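Of the stress and supply lists, which were not called, single genes changed in the 3 knockdowns against uninjected hearts. Of the unfolded protein response and amino acid supply genes, asns rose over all probe sets (0.94, SE 0.20, adjusted p = 0.0489). psat1 (0.69) and phgdh (0.61), which make serine, rose with it when adjusted over the list alone, while the list's median was -0.07 (adjusted p = 0.166, and adjusted p = 0.34 with an estimated correlation). The heat shock genes had a median of 0.17, with 27 of 31 higher and fkbp5 alone called (-1.15, SE 0.23), 1 lower when adjusted over the list alone, and no call of the list (adjusted p = 0.0666, and adjusted p = 0.34 with an estimated correlation). The p53 and apoptosis genes had a median of 0.08 (adjusted p = 0.892) and the oxidative stress genes 0.15 (adjusted p = 0.684), with fthl27 called over all probe sets and 1 higher when adjusted over the list alone, and their adjusted p was 0.927 and 0.892 with an estimated correlation.

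Lipid, immune and blood genes had few members past the threshold. The uncoupling protein gene ucp3 (1.29) and the fatty acid binding gene fabp3 (0.41) rose and ucp2 (-0.61) fell when adjusted over the list alone, with 0 over all probe sets, a list median near 0 (adjusted p = 0.522) and an adjusted p of 0.875 with an estimated correlation. Among interferon and inflammation genes mmp13a and mmp9 rose and the NF-kB inhibitor gene nfkbiaa fell (-0.94) when adjusted over the list alone, with 0 over all probe sets, and the adjusted p was 0.927 with an estimated correlation. In atg7 hearts against control morpholino the same mmp13a and mmp9 and the epicardial cxcl12a (-1.24) passed when adjusted over the list alone, with 0 over all probe sets, and the adjusted p was 0.943 and 0.63 with an estimated correlation. The embryonic globin gene hbbe3 rose by 3.34 and krt4 and cxcl12a of the epicardium list fell (-0.31 and -0.60) when adjusted over the list alone, with 0 over all probe sets and adjusted p of 0.875 and 0.34 with an estimated correlation. rpl22l1 (0.23, SE 0.05) was called over all probe sets and rps27.2 (0.48) rose with it when adjusted over the list alone, with an adjusted p of 0.927 with an estimated correlation. Endocardium and endothelium (-0.11), lysosome (-0.08) and autophagy (0.08) genes had no call and no member past the threshold.

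The tests of eye share, RNA degradation, heart share and the arrangement of arrays were chosen after the result was seen, as were the lists of photoreceptor, lens, neural progenitor and heart-restricted genes.

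The first pattern is that of photoreceptor genes, which lay lower on the knockdown arrays. The mean of 21 photoreceptor genes, which were chosen for the pattern, was 6.18 ± 1.40 (SD, n = 8) on the knockdown arrays and 8.36 ± 0.47 (SD, n = 5) on the control arrays, a difference of -2.19. Signals under 16 were not floored in these means, so their differences have no exact size. Within each knockdown the array numbered 1 lay lowest, at 6.73 on atg5 1, 3.86 on becn1 1 and 4.41 on atg7 1. The others lay at 7.53 and 7.60 (atg5), 6.29 and 7.16 (becn1) and 5.82 (atg7). The arrays numbered 1 are also those of the second pattern below, so the patterns are not separate. A smaller share of eye tissue in the knockdown preparations cannot be told apart, since only 3 of 41 lens genes were measured, with means of 9.68 ± 1.11 (SD, n = 8) and 9.62 ± 0.73 (SD, n = 5), a difference of 0.056. For 5 knockdown arrays (atg5 1, becn1 1, 2, 3 and atg7 1) the GAPDH and acta1 ratios were no higher than the highest control ratios. Their photoreceptor mean was 5.69 ± 1.46 (SD, n = 5), a difference of -2.67 from the control arrays, which argued against more degraded RNA for these arrays. The -2.67 cannot be set against the -2.19 of all 8, since atg5 2 and atg5 3, with the highest knockdown means, were left out. Their means, at most 7.16 on the 5 arrays, lay below the lowest control array (7.66). Since all 8 knockdown arrays did so, that order adds nothing. For the knockdown arrays with higher ratios degradation stays open. Delayed development of the knockdown embryos may be the source, with the 42 neural progenitor genes at a median of 0.36 against uninjected, 2 called over all probe sets and 4 when adjusted over the list alone, though the adjusted p was 0.598 with an estimated correlation, their means on the 8 knockdown and 5 control arrays gave an exact permutation, two-sided, p of 0.0995, and in atg5 hearts against control morpholino their median was -0.02 beside -1.15 for the photoreceptor genes, so delay stays an open hypothesis.

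The second pattern is that of heart genes, which lay higher on the knockdown arrays numbered 1. All 9 heart-restricted genes, cmlc1 (2.99), myl7 (2.76) and tnnt2a (2.47) first, were higher there than on the other arrays of their knockdown. A larger share of heart tissue as the only change was argued against, since it would lower every other tissue. Liver and yolk genes lay higher by 1.71 (SD 0.246 over 3 knockdowns) and exocrine pancreas genes by 1.64 (SD 0.118). Intestine and pronephros (0.61), erythrocyte (0.43) and leukocyte (0.40) genes were higher too. Lens and retina (-1.29), neuron and glia (-0.59), cartilage and neural crest (-0.53) and epidermis (-0.49) genes were lower, as a larger heart share would make them. A larger heart share beside other changes therefore stays open. Normalization between arrays was argued against, since the median difference was 1.88 with it and 1.825 without it. Chance cannot be excluded, since 1 of 18 arrangements was as large as the real 1.89, the highest other was 1.09, and 18 are too few for a share under 0.05.

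The third pattern is that 126 probe sets were called for the 3 knockdowns against uninjected and 0 against control morpholino (12 without the arrays numbered 1, 13 on the deposited scale). With the replicate block probe sets were called in both comparisons, so the contrast with 0 depends on the model. An effect of injection shared by control morpholino and the knockdowns may account for part of it, but the test cannot decide this. Over the called probe sets control morpholino moved with a slope of 0.299. The simulated slope was 0.0745 (0.0128 to 0.148) with control morpholino at the uninjected level and 0.970 at the knockdown level. The simulation drew each probe set independently, while real probe sets move together, so its range is too narrow. Whether fewer control arrays made the difference cannot be told apart, since 1 uninjected array left out gave 0, 184 and 0. Chance cannot be excluded: 5 of 100 splits of the 11 arrays, the real one among them, had as many probe sets as the real 126, with 1130 as the highest other, for becn1 1, atg7 1 and atg7 2, and 5 of 100 called as many lists as the real 18, with 21 as the highest other. The 10 splits of the atg5 and becn1 arrays decide nothing, since the real count and the highest other were 0.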
